A study of Mus musculus with 41 samples.

How the data were processed

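RNA from the hippocampus of 41 male mice of the inbred C57BL/6J strain was measured on Affymetrix mouse expression arrays, with 1 biotin-labelled sample and 1 array per mouse. The labels rank the mice by learning and memory. Testing began at an age of 10 weeks and covered 5 cognitive tests, which gave 11 parameters. Complete data existed for 39 mice. The tests ran as Barnes maze in weeks 10 to 11, radial maze in weeks 12 to 14, T-maze in weeks 15 to 19, fear conditioning in week 33 and passive avoidance in weeks 37 to 38. RNA was taken 1 month after the last test. A mouse counted as low, medium or high when 2 ranking systems placed it in the same class. The groups held 8 low, 12 medium and 5 high mice, 14 mice with an inconsistent ranking and 2 with incomplete behavioural data. The second mouse with an inconsistent ranking also carries a description as consistently medium. It stayed in the inconsistent group, and an alternative moved it to the medium group.

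The submitters' processing notes name Partek and RMA without versions, and the step that made the deposited values is not given in the sources used here. The deposited values are linear probe set intensities by their range, from 0.0112 to 13550, and array medians ran from 22.4 to 55.2, so the authors' values were neither on a log2 scale nor brought to a common distribution. The test had been planned for log2 values. Intensities were therefore quantile-normalized over the 41 arrays and put on a scale of log2(intensity + 16). The offset of 16 was chosen after the unit had been seen. Differences below are on this scale and understate changes of dim genes. The tables hold 45101 probe sets, of which 64 are array controls. The brighter part of the remaining 45037 by the mean over all arrays, 22519 probe sets at or above the median, was tested. No coordinates are given, since no genome was used here. Precision was limited by the number of arrays.

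Gene symbols came from the platform annotation, where 34945 probe sets had 1 symbol, 932 had several and 9160 had none. Entrez identifiers of 34754 of 34958 probe sets were found in the reference gene table, and 0 symbols changed. Probe sets with several symbols were not named.

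The 25 low, medium and high arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group and moderated statistics, and contrasts were adjusted by Benjamini-Hochberg with a threshold of 0.05. A moderated F test asked for any difference among the groups, and a slope over classes coded 1, 2 and 3 asked for an ordered trend. Gene lists were tested with camera at a preset correlation of 0.01 on 11218 genes, each at its brightest probe set. Camera with the correlation estimated per list and fry, a rotation test, were run beside it. Of 38 lists, 37 had at least 5 measured members. The red blood cell list had 2 and was not tested. Mean list levels per array were compared by two-sided exact permutation tests.

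The comparisons, lists, tests and most alternatives were fixed before the data were examined. So was the rule for named genes: up to 12 per direction past the threshold for high against low, and a smaller share for the other comparisons, with unfilled places up to 8 going to the smallest unadjusted p, up to 3 leading members of each list described, and 15 genes named whatever their values, of which 1 is not reported here. Genes with a near-identical copy, such as Hspa1a and Hspa1b, were read as uncertain.

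The labels give no processing batch. Bacterial and phage spike-in control probe sets separated the arrays into 3 batches of 7, 10 and 24 arrays, a grouping made after the values were seen. Results are given with this batch as a block and within batches. Alternatives fixed in advance covered the filter, normalization, variance model, array weights, 1 probe set per gene, the arrays in the fit, covariates, the replicate number as a block and leaving out each array in turn. Alternatives added after seeing the data were no normalization between arrays, offsets of 1 and 50, the batch as a block, batch 3 alone, and leaving out arrays with bright choroid plexus markers. The counts were set against 100 splits of the 25 arrays, the real one included, and, chosen after the result was seen, against 100 splits with group labels shuffled within the batches. The steps were tested on simulated data with 22519 probe sets. For high against low, 28.0% of probe sets changed by 0.25 on the log2 scale, 88.0% of those changed by 0.5 and 98.0% of those changed by 1 were recovered. For high against medium the shares were 22.0%, 78.0% and 94.0%, and for medium against low 28.0%, 92.0% and 100.0%. False calls made up 4.3%, 7.0% and 5.9% of the calls in these comparisons, the latter 2 above the 5% that the threshold aims at. The simulated noise was independent between probe sets, without batches or outlying arrays, and 50 probe sets were changed at each size. These shares therefore need not hold for the real arrays, where few probe sets were called.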

Results

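Gene expression in the hippocampus was measured in 41 inbred mice that shared their genetic background and differed in how they ranked in learning and memory. The series concerns genes and pathways under epigenetic control in general cognitive ability. Of the ranked mice, 8 were consistently low, 12 medium and 5 high. The rankings of 14 mice were inconsistent, and 2 mice had incomplete behavioural data. Pairwise correlations of the arrays ran from 0.949 to 0.993 with a median of 0.986, and the lowest was 0.967 without medium replicate 9, which stood apart. Median signals before normalization ran from 22.4 to 47.0 in the low group, 29.5 to 53.2 in the medium group and 25.9 to 46.9 in the high group.

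The comparison of high with low mice asked which hippocampal genes separate the ends of the cognitive ranking. Bloc1s2 and Inip were higher in the high group and were the 2 probe sets of 22519 past the threshold. Bloc1s2 encodes a subunit of complexes that form and position lysosome-related organelles. Its level was 9.29 ± 0.09 (SD, n = 5) in high and 8.94 ± 0.07 (SD, n = 8) in low mice, a log2 difference of 0.35 ± 0.05 (SE) and a fold of 1.28, with a limma adjusted p of 0.00612. Inip, part of a complex that binds single-stranded DNA, was at 6.92 ± 0.02 in high and 6.60 ± 0.09 in low mice, a log2 difference of 0.32 ± 0.05 with the same adjusted p. For both genes the 5 high arrays lay above every low array, and medium mice averaged 8.98 and 6.73. The other Inip probe sets tested differed by 0.04 and 0.20 and did not pass.

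None of the next genes by p passed. Among those with higher means in high mice were Rbm14, an RNA-binding coactivator (log2 difference 0.39, limma adjusted p 0.130), Elp4 of the Elongator complex (0.32), Pop5, a ribonuclease P subunit (0.29), the collagen prolyl hydroxylase subunit P4ha2 (0.41), the B cell linker Blnk (0.44) and the lysosomal trafficking regulator Lyst (0.39). Those with lower means included the neuropeptide Y receptor Npy1r (-0.48), the nuclear pore gene Nup98 (-0.41), Aifm3 (-0.56), 2900052L18Rik (-0.32), the phosphodiesterase Pde5a (-0.37), the deadenylase Parn (-0.32), Ammecr1l (-0.32) and Rasl12 (-0.29). At an unadjusted p under 0.05 there were 1837 probe sets. With the spike-in batch as a block, Bloc1s2 differed by 0.36 and Inip by 0.33, both at a limma adjusted p of 0.00653. Bloc1s2 passed without Inip under a variance trend with robust fit, with all 41 arrays in the fit, and with the mouse of contradictory description in the medium group. It also passed with 1 probe set per gene and with fewer, brighter probe sets kept, in fits that did not hold the called Inip probe set. Within batch 2, of 1 high and 2 low arrays, the differences were 0.18 and 0.22, and within batch 3, of 4 and 5 arrays, 0.41 and 0.37. Batch 1 held no high array. Fits on the 2 groups alone, on batch 3 alone, without normalization between arrays or without the arrays bright in choroid plexus markers called 0 probe sets by limma, with 2000, 1741, 289 and 1287 at an unadjusted p under 0.05, while over all settings other than leaving out an array the difference stayed between 0.31 and 0.46 for Bloc1s2 and between 0.21 and 0.37 for Inip. By limma on the 2 groups alone both genes had an adjusted p of 0.236, and the exact rank-sum test also called 0, with 2056 at an unadjusted p under 0.05.

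**Figure D1:**
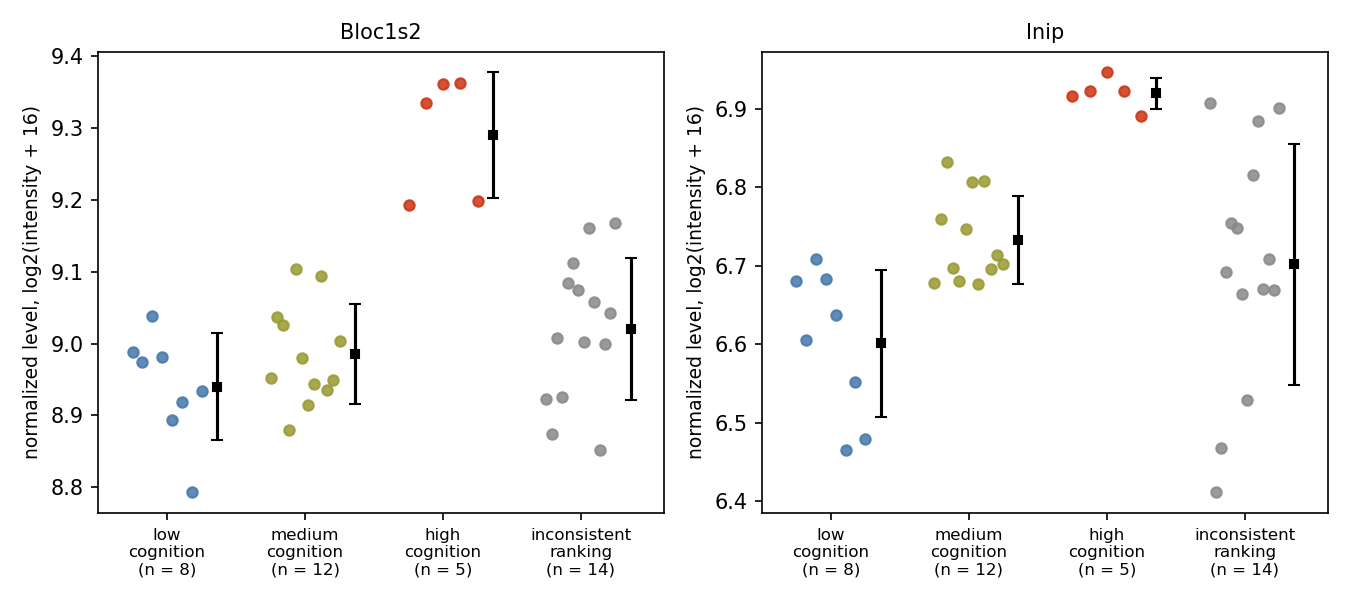
Levels of Bloc1s2 and Inip per array, as log2(intensity + 16) after normalization, by group; points are arrays and squares with bars are the mean and SD. The high arrays lie above all low arrays for both genes.

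Chaperone genes were higher as a group in high mice. Of 28 measured genes of the heat shock and unfolded protein response, 25 had a difference above 0, with a median of 0.16, and camera gave an adjusted p of 3.25e-08 over 37 lists. With an estimated correlation the adjusted p was 0.931. Fry, which compares a list with no other genes, gave an adjusted p of 0.280 for a shift in 1 direction and 0.0315 for change in either. Adjusted over the list alone 10 members passed, and over all tested probe sets 0 did. The cytosolic chaperone Hsph1 differed by 0.25 ± 0.07 (SE) and the secreted endoplasmic reticulum stress factor Manf by 0.42 ± 0.12, both at a limma p of 0.0253 adjusted over the list alone. The inducible Hsp70 genes Hspa1b (0.70 ± 0.22) and Hspa1a (0.48 ± 0.16) are near-identical copies, so their separate values are uncertain. The mean level of the list was 9.96 ± 0.15 (SD, n = 5) in high, 9.76 ± 0.08 (n = 8) in low and 9.76 ± 0.11 (n = 12) in medium mice. An exact permutation test of the list mean gave p = 0.00389 for high against low, and 0.153 after adjustment over 63 tests. The median difference of the list was 0.16 with the batch as a block, 0.29 in batch 2 and 0.14 in batch 3.

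Choroid plexus markers were lower as a group in high mice, all 11 of them, with a median log2 difference of -1.03 and a camera adjusted p of 0.000307. With an estimated correlation the adjusted p was 0.985, and 0 members passed adjusted over the list alone. Ttr, the transthyretin of the choroid plexus, differed by -1.50 ± 0.97 (SE), although it had the same value of 13.40 on 3 bright arrays, where it was among the top probe sets and normalization gives equal ranks equal values. Slc13a4 differed by -1.10 ± 0.62, Igfbp2 by -0.75 ± 0.43, Clic6 by -1.56 ± 0.93 and Kl by -0.78 ± 0.61. The list mean lay between 6.23 and 6.76 in the high arrays, while 3 low and 4 medium arrays lay at 8.32 or higher. The exact permutation p of the list mean was 0.124, and 0.791 adjusted over 48 tests. The list's median was -0.89 with the batch as a block, -0.24 in batch 2 and -0.94 in batch 3.

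Proteasome genes also rose as a list, 25 of 31 above 0 with a median of 0.05 and a camera adjusted p of 0.0437, led by Psmb4 (0.12), Psmd14 (0.11) and Psmd11 (0.13). This call was lost with an estimated correlation, where the adjusted p was 0.985, and with the batch as a block, where the median was 0.03 and the adjusted p 0.149. Within batches 2 and 3 the medians were 0.05 and 0.02. It was also lost without any of low replicates 1 to 4 or high replicates 1, 3 and 4, at medians of 0.03 to 0.04 and camera adjusted p of 0.0526 to 0.109. Of 100 splits of the arrays into groups of the same sizes, 64 called at least as many lists as the 3 here. Glucocorticoid-responsive genes came next without passing, with 17 of 21 above 0, a median of 0.10 and an adjusted p of 0.0594. Klf9 (0.24), Fam107a (0.16) and Angptl4 (0.23) led them.

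**Figure D2:**
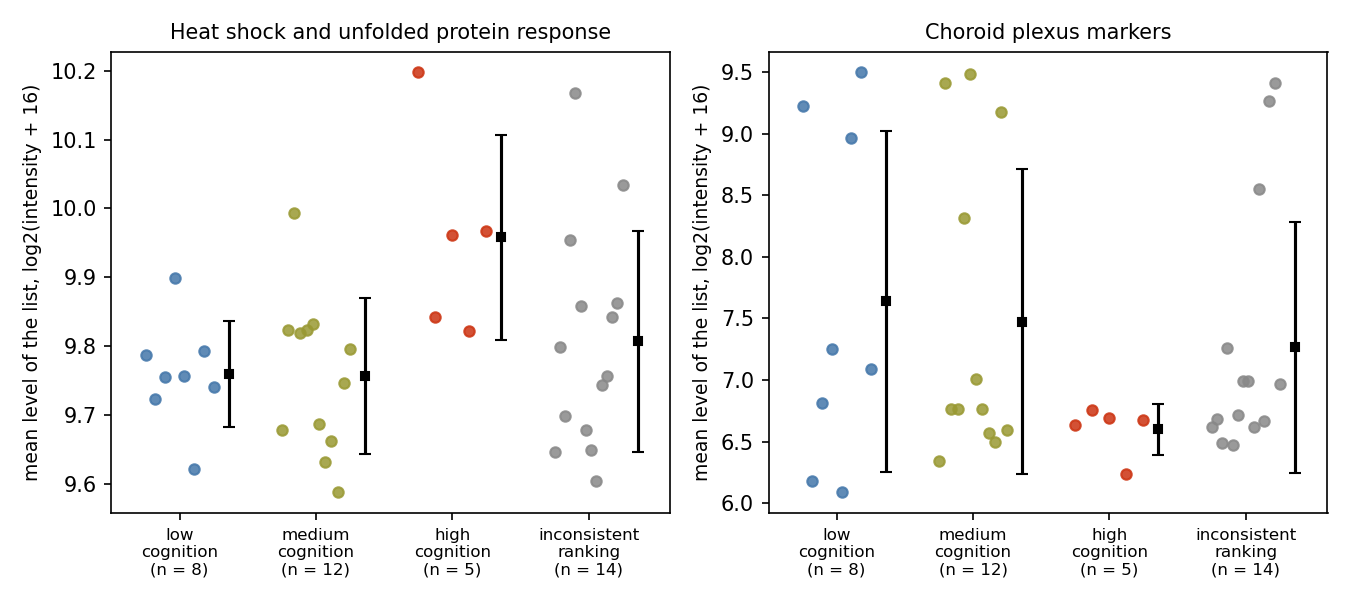
Mean level per array, as log2(intensity + 16), of the heat shock and unfolded protein response genes and of the choroid plexus markers, by group; points are arrays and squares with bars are the mean and SD. High arrays lie between 9.82 and 10.20 for the chaperone list and between 6.23 and 6.76 for the choroid plexus markers.

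**Figure D3:**
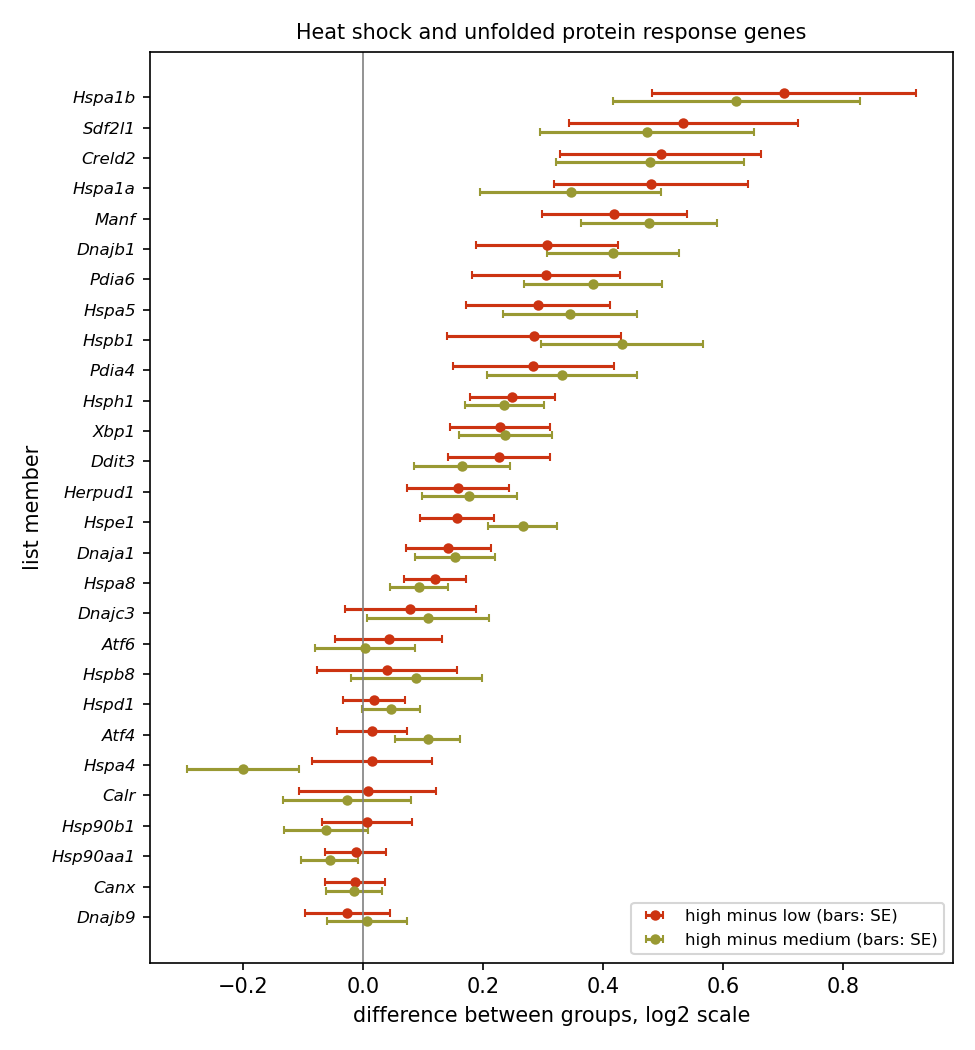
Difference of each of the 28 measured heat shock and unfolded protein response genes between high and low and between high and medium mice, on the log2 scale, with bars for the SE. Against low mice 25 members lie above 0, and against medium mice 23.

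Transcripts of the machinery of epigenetic regulation showed small differences between high and low mice. The series concerns genes under epigenetic control, and these transcripts do not test such control, since no epigenetic mark was measured here. The 4 lists of DNA methylation genes, histone acetyltransferases, histone deacetylases, and histone methyltransferases with demethylases did not pass, at camera adjusted p from 0.817 to 0.986. The acetyltransferases Crebbp (0.18 ± 0.06 SE) and Ncoa1 (0.28 ± 0.09) passed limma's test adjusted over the list alone, at p of 0.0415 and 0.0419, and not over all probe sets. Dnmt1 differed by -0.08, Dnmt3a by 0.04 and Hdac2 by 0.01. Genes of plasticity and of cell types did not pass either, with differences for Fos of 0.03, Arc -0.12, Bdnf 0.18, Grin2b -0.09, Camk2a -0.12, Ppp1r1b -0.31, Prox1 0.09, Gfap -0.19 and Mbp -0.02. Limma adjusted p ran from 0.626 to 0.993 for these genes, and the SE was 0.43 for Fos, 0.32 for Arc and 0.23 for Ppp1r1b. The Mbp probe set, 1 of 8 tested for the gene, was among the brightest, where normalization gives equal ranks equal values. It read 13.10 on each of low replicates 1, 3, 4 and 6, so its small difference says little about the transcript.

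The comparison of high with medium mice asked what sets the best learners apart from the middle of the ranking. In it 4 probe sets were higher and 3 lower. P4ha2 rose by 0.48 ± 0.09 (SE) on the log2 scale, Rbm14 by 0.40 ± 0.07, Elp4 by 0.35 ± 0.06 and Bloc1s2 by 0.31 ± 0.05. The membrane cytoskeleton gene Epb41l1 fell by 0.47 ± 0.08, Crocc, the ciliary rootlet gene, fell by 0.47 ± 0.08 and the cyclin Ccni fell by 0.30 ± 0.05. Each of the 7 had all 5 high arrays on the same side of the medium mean, which is likely for genes chosen by this comparison. High and medium arrays overlapped for P4ha2, Epb41l1 and Crocc and did not for Rbm14, Elp4, Bloc1s2 and Ccni. The limma adjusted p was 0.0223 for Bloc1s2 and 0.0280 for the other genes, and 2971 probe sets had an unadjusted p under 0.05. Inip differed by 0.19 and the growth factor receptor Fgfr3 by -0.30, and neither passed, at limma adjusted p of 0.115 and 0.0827.

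Other probe sets of the same genes moved less. The remaining tested probe sets differed by 0.11, 0.04 and 0.02 for Rbm14, by -0.18 and 0.02 for Epb41l1 and by -0.04, -0.19 and -0.25 for Ccni. With the batch as a block, Rbm14 (0.43, limma adjusted p 0.0218), Bloc1s2 (0.32, 0.0158) and Ccni (-0.33, 0.0114) passed, while Elp4 (0.35, 0.0568), P4ha2 (0.43, 0.0941), Epb41l1 (-0.43, 0.0941) and Crocc (-0.46, 0.0941) did not. Within batch 2, of 1 high and 5 medium arrays, the differences were 0.72 for P4ha2, 0.36 for Rbm14, 0.39 for Elp4, 0.20 for Bloc1s2, -0.18 for Epb41l1, -0.42 for Crocc and -0.24 for Ccni. In batch 3, of 4 and 5 arrays, they were 0.32, 0.44, 0.37, 0.34, -0.50, -0.48 and -0.35 in that order, and batch 1 held no high array. The medium arrays of batch 2 included medium replicate 9, which stood apart. Centring arrays on their medians called 928 probe sets, 883 of them higher and 45 lower, so that 95.2% were higher against 57.1% of the 7. The median difference of all tested probe sets was then 0.0651, against 0.0053 in the main fit, so a shift of all probe sets goes with these calls. Without the brightness filter none of the 7 passed, and the 1 call among 45037 was a probe set without a single symbol. Fits on the 2 groups alone, on batch 3 alone, without normalization or without the arrays bright in choroid plexus markers called 0 by limma, with 3083, 1614, 1727 and 2529 at an unadjusted p under 0.05, and the exact rank-sum test called 0, with 3482. The count was also 0 without any of medium replicates 4, 7 and 10 or high replicates 2, 3 and 4, 1 without medium replicate 8, 3 without high replicate 5, 15 without medium replicate 12 and 16 without medium replicate 3. With each array left out in turn the differences ran from 0.29 to 0.33 for Bloc1s2, 0.36 to 0.43 for Rbm14, 0.32 to 0.38 for Elp4, 0.44 to 0.53 for P4ha2, -0.55 to -0.39 for Epb41l1, -0.51 to -0.42 for Crocc and -0.32 to -0.28 for Ccni. Over the other settings they ran wider, from 0.15 to 0.41, 0.23 to 0.48, 0.15 to 0.40, 0.29 to 0.59, -0.66 to -0.40, -0.66 to -0.32 and -0.44 to -0.18 in that order.

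Chaperone genes were higher in high mice than in medium mice, in a comparison that uses the same 5 high arrays as the comparison with low mice. Of the 28 in the heat shock and unfolded protein response list 23 were above 0, with a median of 0.17 and a camera adjusted p of 1.18e-07, against an adjusted p of 0.687 with an estimated correlation. Adjusted over the list alone 12 passed. Hspe1 differed by 0.27 ± 0.06 (SE), Manf by 0.48 ± 0.11 and Dnajb1 by 0.42 ± 0.11. The same list had medians of 0.18 with the batch as a block, 0.34 in batch 2 and 0.11 in batch 3. Activity-dependent immediate early genes were higher as a list, with 18 of 24 above 0, a median of 0.20 and an adjusted p of 0.0292 that became 0.770 with an estimated correlation. The mean level of this list was 8.34 ± 0.14 (SD, n = 5) in high, 8.19 ± 0.29 (n = 12) in medium and 8.35 ± 0.27 (n = 8) in low mice. High mice were thus near low mice in this list, and the medium mean was the lowest. Among its members Bdnf (0.35 ± 0.08) passed adjusted over the list alone, at a limma p of 0.00822, and Btg2 (0.32) and Homer1 (0.12) did not. Proteasome genes (26 of 31, median 0.06) and respiratory chain genes (32 of 44, median 0.04) were also higher as lists, although with an estimated correlation both had an adjusted p of 0.687. Without normalization between arrays their medians turned to -0.09 and -0.08, where the median of all tested probe sets was -0.17. Sdhd, at 0.19, passed adjusted over the respiratory chain list alone, and Psmb4 (0.13), Psmd6 (0.12) and Psmd14 (0.12) led the proteasome list without passing.

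Choroid plexus markers were lower, all 11 of them, with a median of -0.76 and an adjusted p of 0.770 with an estimated correlation. Synaptic vesicle genes were lower in 18 of 23, with a median of -0.08 and an adjusted p of 0.770 with an estimated correlation. Their median turned to 0.05 when arrays were centred on their medians, where that of all tested probe sets was 0.07. Sv2a (-0.26), Slc32a1 (-0.30) and Vamp1 (-0.18) led the vesicle list. Dopamine and striatal markers were lower in 9 of 11, with a median of -0.11, and an adjusted p of 0.687 with an estimated correlation. Rgs9 (-0.40), Adcy5 (-0.23) and Ppp1r1b (-0.51) led them. Medium replicate 9 had a striatal marker mean of 8.91, above the 8.35 that was the highest of the other arrays. Camera adjusted p were 0.00120 for the proteasome, 0.0107 for choroid plexus markers and 0.0292 for each of the immediate early, respiratory chain, synaptic vesicle and striatal lists. None of the 7 lists passed with an estimated correlation or in fry's directional test. Fry's test for change in either direction passed for the chaperone list (adjusted p 0.000731) and for histone methyltransferases with demethylases (0.0372), whose median was 0.0043 with 16 of 30 above 0 and a camera adjusted p of 0.751.

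With the batch as a block, the immediate early list (median 0.21) and the proteasome list (0.05) kept their calls beside the chaperones, at camera adjusted p of 0.000461 and 0.0400. The synaptic vesicle (-0.04, p 0.0925), striatal (-0.11, p 0.0720), choroid plexus (-0.65, p 0.0571) and respiratory chain (0.04, p 0.138) lists lost theirs. Within batch 2 the medians were 0.27 for immediate early, 0.08 for proteasome, -0.14 for synaptic vesicle, -0.19 for striatal, -0.86 for choroid plexus and 0.06 for respiratory chain genes. Within batch 3 they were 0.18, 0.04, 0.0026, -0.08, -0.48 and 0.02, so that the synaptic vesicle list turned its sign there. Medium replicate 9 was among the medium arrays of batch 2. Its striatal mean was 8.91, against 8.18 to 8.30 in the other medium arrays of that batch and 8.20 in high replicate 1. Its synaptic vesicle mean was 10.71, against 10.22 to 10.33 and 10.20. The contrast between batches 2 and 3 in these 2 lists was therefore not separated from this array. Without medium replicate 9 the synaptic vesicle (-0.03, p 0.133), striatal (-0.09, p 0.112) and respiratory chain (0.03, p 0.112) lists did not pass camera's test, nor did these 3 without high replicate 1, the vesicle list without high replicates 2 or 4, or the striatal list without high replicate 2, at adjusted p of 0.0509 to 0.0739. The immediate early list did not pass without medium replicates 6, 7, 8, 10 or 12 or high replicates 1 or 5, at medians of 0.16 to 0.20 and adjusted p of 0.0505 to 0.173. Of 100 splits of the arrays, 21 called at least as many lists as the 7 here. Among single genes of other lists, the histone demethylase Kdm3a (0.27), the acetyltransferase Crebbp (0.18) and the neurogenesis genes Neurod1 (0.39), Sox11 (0.45) and Ccnd2 (0.29) were higher and passed limma's test adjusted over their list alone, at p from 0.00426 to 0.0257. Bdnf passed in the growth factor list too (p = 0.00343), by the same probe set as in the immediate early list, which adds no separate evidence. Lower genes that passed in this way were Fgfr3 of the astrocyte list (-0.30, p = 0.00055), Nrg3 of the growth factor list (-0.18, p = 0.0358) and Ptn of the dentate granule list (-0.18, p = 0.0431). These p were adjusted within 1 list each and not over the lists, and none of these genes passed over all tested probe sets.

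Medium and low mice, which differ in the lower part of the ranking, had no probe set past the threshold. The limma test called 0 of 22519, with 698 at an unadjusted p under 0.05 and a smallest adjusted p of 0.998, and the exact rank-sum test called 0, with 667. Genes of the smallest p did not pass: the transcription factor Sox5 (0.40), Elmod3 (0.26), Gm8273 (0.26) and the mitochondrial RNA polymerase Polrmt (0.18) had higher means in medium mice, and Tsc22d1 (-0.40), Lsm8 (-0.21), the neuronal RNA-binding gene Elavl2 (-0.15) and Cnn3 (-0.24) lower ones.

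Immediate early genes were lower as a list in medium than in low mice, with 20 of 24 below 0, a median of -0.16 and a camera adjusted p of 1.93e-05, against an adjusted p of 0.870 with an estimated correlation. Btg2 (-0.39), Bdnf (-0.17) and Nr4a3 (-0.29) led them, and none passed adjusted over the list alone. Ependymal markers were lower in 8 of 8, with a median of -0.12 and a camera adjusted p of 0.00920, against an adjusted p of 0.870 with an estimated correlation. Rarres2 (-0.21), Enkur (-0.11) and Cfap126 (-0.25) led them. With the batch as a block the medians were -0.15 and -0.10, at camera adjusted p of 8.46e-08 and 0.0485. In batches 1, 2 and 3 they were -0.05, -0.24 and -0.14 for immediate early genes and -0.15, -0.15 and -0.05 for ependymal markers, from 2 medium and 1 low, 5 and 2, and 5 and 5 arrays. Batch 2 held medium replicate 9 here too. The ependymal list did not pass without low replicates 1, 6 or 7 or medium replicate 9, at medians of -0.12 to -0.08 and camera adjusted p of 0.0542 to 0.275, and 93 of 100 splits of the arrays called at least as many lists as the 2 here.

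Over the 3 groups together, limma's F test called 2 probe sets, with a smallest adjusted p of 0.0129 and 1940 at an unadjusted p under 0.05. An ordered trend from low through medium to high was found for 1 probe set, Inip, with an adjusted p of 0.0118. The trend count was 1 in 7 of 19 other settings and 0 in the rest. Among the latter, the fits with 1 probe set per gene and with fewer, brighter probe sets did not hold the called Inip probe set. The count was also 0 without any of high replicates 1 to 4, and the other Inip probe sets had adjusted p of 0.837 and 0.979 in limma's trend test. No marker list of a cell type or neighbouring tissue passed in mean level. Exact permutation tests over 48 comparisons called 0, with a smallest adjusted p of 0.791 and 1 at an unadjusted p under 0.05, the striatal markers of high against low mice (exact p = 0.0303). Medium replicate 9 had the highest neocortex marker mean, 9.11, and the lowest dentate granule marker mean, 7.37.

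**Figure D4:**
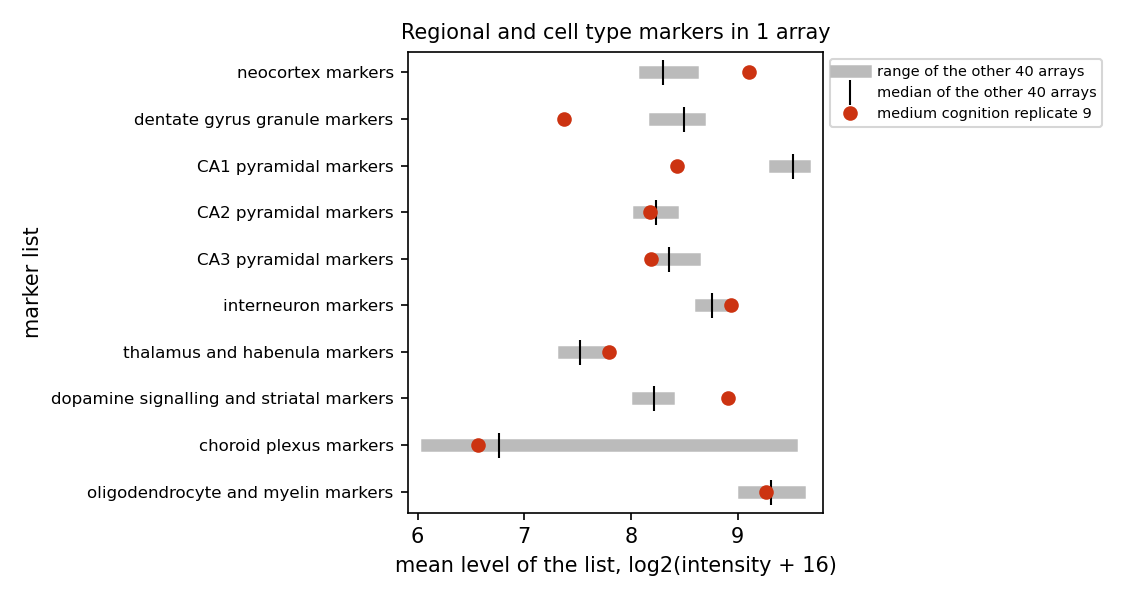
Mean level of 10 marker lists, as log2(intensity + 16), in medium replicate 9 (points) beside the range (bars) and median (ticks) of the other 40 arrays. Its neocortex markers lie at 9.11 and its dentate granule markers at 7.37, outside the range of the others.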

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

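Chosen only after the result was seen were the tests of batch on the chaperone and choroid plexus patterns, of batch on the split into bright and dim choroid plexus arrays, of choroid plexus tissue, and both tests of medium replicate 9; the others were planned. Single arrays stood apart within their group for 7 of 210 groups of arrays examined, where chance gives about 1 in 20.

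Nup98 was at 7.12 in low replicate 5, while the other low arrays lay between 6.64 and 6.85. Pde5a was at 6.19 in high replicate 1, and the other high arrays lay between 5.90 and 5.94. Fgfr3 was at 9.57 in low replicate 3, against 9.20 to 9.36 in the rest of the group. Polrmt was at 7.87 in low replicate 5, below the range of 8.18 to 8.37 in the others. Tsc22d1 was at 10.33 in low replicate 5, above the range of 9.41 to 9.83. The choroid plexus marker mean was 6.23 in high replicate 4 and between 6.63 and 6.76 in the other high arrays. The mean of cholesterol synthesis genes was 8.56 in low replicate 8 and between 8.34 and 8.43 in the other low arrays.

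Chaperone genes were higher in high than in low mice, by 0.20 ± 0.06 (SE) in the list mean. The difference was 0.2084 ± 0.06 with the batch as a block and 0.2213 ± 0.06 with array brightness and the actin 3' to 5' ratio as covariates, which argues against each as the whole cause. With the mean of glucocorticoid-responsive genes as covariate it was 0.1506 ± 0.06, or 75.9% of the former value, narrowly above the share set in advance for this verdict. This argues against a stress state shared with those genes as the whole cause, while a partial share may remain. A difference tied to cognitive rank was not tested apart from these causes and stays open, as does handling before death. Chance is not excluded either. The list mean did not pass the exact permutation test after adjustment, and camera's adjusted p was 0.931 with an estimated correlation. Of 100 splits of the arrays, 64 called at least as many lists as the 3 of high against low.

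Choroid plexus markers were lower in high mice, and the 11 bright arrays of all 41 were 3 low, 4 medium, 3 inconsistent and 1 incomplete, with 0 high ones. Choroid plexus tissue carried along in some dissections is a candidate explanation: the 11 markers had a median pairwise correlation of 0.9129 over 41 arrays, and Ttr reached 13.40 at its highest, on 3 arrays. A labelling and hybridisation batch is argued against as the whole cause of this division, since over all 41 arrays, unranked mice included, every spike-in batch held bright and dim ones (3 and 4, 2 and 8, and 6 and 18), the fewest on either side being 2. With the batch as a block the list's camera call held against low mice (adjusted p 0.00289) and was lost against medium mice (0.0571), and with an estimated correlation and no block it was lost against both (0.985 and 0.770), while the list mean differed from low mice by -0.9089 ± 0.69 (SE), against -1.04 ± 0.67 without the block, so a share of batch in the group difference stays open. A difference in the choroid plexus linked to rank was not tested and stays open, and chance is not excluded either.

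Medium replicate 9 stood apart from the other 40 arrays in regional markers, as the plot of its marker levels shows. Its neocortex marker mean was 9.11, above the highest other array by 0.5335, with Lamp5 at 11.21 and Foxp2 at 8.05 where the others reached 9.53 and 6.21 (both chosen after their values were seen), while Bcl11b (9.89) and Lmo3 (9.56) of that list lay below all others, and its dentate granule mean was 7.37 against a lowest other of 8.23, which is consistent with neocortex in the sample. Striatal markers exceeded the highest other array by slightly more (8.91 against 8.35), interneuron and thalamus markers were also the highest of 41 arrays and CA1 and CA3 markers the lowest, so the tissue is not settled. RNA degradation may also contribute: its Gapdh log2 3' to 5' ratio of -0.3556 and its actin ratio of 0.83 were the highest of all arrays. Neither was excluded, and no biological explanation was tested for a single mouse.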

How the results depend on the processing

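Alternatives chosen only after the values were seen were no normalization, the offsets of 1 and 50, the spike-in batch as a block, batch 3 alone and leaving out the arrays bright in choroid plexus markers; the others were planned. The results depended strongly on the processing, and the cause was not tested unless stated. Counts of probe sets are given for high against low (2), high against medium (7), any difference (2) and trend (1), and of lists for high against low (3), high against medium (7) and medium against low (2). For probe sets in medium against low, and for marker levels, the count was 0 under every alternative run. Counts of 0 in the 4 probe set results came from batch 3 alone (lists 2 for high against medium, 1 for medium against low), from no normalization (lists 7 for high against low and 7 for medium against low) and without the bright choroid plexus arrays (lists 1 for medium against low). With the replicate number as a block the 4 counts were also 0, with 1 list for medium against low. The labels do not say that the numbers pair the mice. Same-numbered arrays correlated at -0.10 to 0.01, -0.10 to 0.10 and -0.17 to 0.14, and each array correlated best with its own number in 0 of 5, 3 of 5 and 0 of 8. The 3 of 5, for high against medium, leave pairing open there. The 2 groups alone and the exact rank-sum test gave 0 for both high comparisons; the smallest p the rank-sum test can give was 0.00155 and 0.000323. No filter gave 1 for high against medium, a probe set without a single symbol that was not among the 7, and 0 for trend. Keeping fewer, brighter probe sets gave 1, 11 and 0 (trend), and lists 1, 3 and 1. Median centring gave 5, 928 and 62 (any), and lists 8 and 4 (medium against low). The variance trend with robust fit gave 1, 15 and 0 (trend). The unmoderated model gave 15 for high against medium. Array weights gave 3 for high against low, 354 for high against medium and 33 for any difference, and 1 list for medium against low. With 1 probe set per gene high against low gave 1 and trend 0. The called Inip probe set was left out of this fit and of that with fewer, brighter probe sets, so neither could call it. All 41 arrays gave 1, 23, 1 and 0. Moving the mouse with the contradictory description gave 1 for high against low, 1 for any difference and 0 for trend. The first principal component as covariate gave 1 for high against medium, and lists 4 and 1 (medium against low). The choroid plexus covariate gave 4 and 0 (trend), and 1 list for high against low. The batch block gave 4 for high against medium, 5 for any difference and 3 lists for high against medium. Offset 50 gave 1 for any difference and 0 for trend. Camera with an estimated correlation and fry's directional test gave 0 lists in each comparison. Leaving out each array in turn gave 2 to 2 for high against low, 0 to 16 for high against medium, 0 to 0 for medium against low, 0 to 4 for any difference and 0 to 1 for trend. Lists ranged from 2 to 6, 3 to 9 and 1 to 6. High against medium fell to 0 without medium 4, 7 or 10 or high 2, 3 or 4, to 1 without medium 8, to 3 without high 5 and to 4 without medium 1 or high 1, and was 15 without medium 12 and 16 without medium 3. Trend was 0 without high 1, 2, 3 or 4. Lists for high against low were 6 without low 5 and 5 without high 2. For high against medium they were 4 without medium 9 and 3 without high 1. For medium against low they were 1 without low 1, 6 or 7 or medium 9, 4 without low 3 or medium 8, and 6 without low 5. Of the medians, choroid plexus markers turned to 0.0343 (high against low) and 0.0096 (high against medium) with their own level as covariate, by construction. Synaptic vesicle genes in high against medium turned to 0.0484 with median centring and 0.0026 in batch 3 alone, and without normalization respiratory chain genes turned to -0.0754 and proteasome genes to -0.0850. Without normalization the median of all probe sets shifted by -0.17 for high against medium and 0.11 for medium against low. With median centring it shifted by 0.07 for high against low and for high against medium. Of the other values, 2849 kept their direction and their side of the threshold, 217 lost a call, 33 gained one and 32 changed sign without a call. Most values had no call in the main fit and counted as kept when they stayed uncalled with the same sign. The 2849 therefore do not measure how stable the calls were, since only called values could lose a call. Those that changed sign without a call were Fos (-0.28 to 0.28), Kl (up to 0.20), Arc, Dnmt3a, Hdac2, Camk2a, Prox1 and Mbp in high against low, Homer1, Psmd6 and Psmd14 in high against medium without normalization, and the choroid plexus level in medium against low. The heat shock list kept its call in high against low under every alternative except the estimated correlation and fry's directional test, with medians from 0.12 to 0.28. Background was not measured here, and probe sets dimmer than the median were tested only in the fit with no filter.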

Other observations

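The relation of chaperone and glucocorticoid-responsive genes across arrays, and its test within batches, were chosen only after the result was seen; so were the splits within batches, while the comparisons with other splits were planned.

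The mean of the chaperone list lay between 9.60 and 10.17 in the 14 mice with an inconsistent ranking and was 9.83 and 9.88 in the 2 with incomplete data. Choroid plexus markers lay above 8.32 in 3 of the former and 1 of the latter. Bloc1s2 averaged 9.02 ± 0.10 (SD, n = 14) and Inip 6.70 ± 0.15 in the inconsistent mice.

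Some lists fell short of the threshold in the high mice. Myelin and oligodendrocyte markers were below 0 against low mice in 13 of 16 (camera adjusted p 0.0926) and meningeal fibroblast markers in 9 of 10 (0.111). Cytosolic ribosomal proteins were above 0 against medium mice in 21 of 30 (0.0606).

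Across all 41 arrays the chaperone list moved with glucocorticoid-responsive genes. Pearson's r was 0.602 (permutation p = 3e-05, adjusted p = 0.00108 over 36 relations) and Spearman's rho 0.591 (permutation p = 8e-05, adjusted 0.00216). Without the 2 arrays farthest from the median, r was 0.680. Within batches 1, 2 and 3 it was 0.872, 0.725 and 0.5078, with a permutation p of 0.0112 in batch 3, which argues against batch as the whole cause. Splicing factors came next, with r = 0.475 (permutation p = 0.00171, adjusted 0.0308) and rho = 0.578 (permutation p = 0.00012, adjusted 0.00216), and r of 0.578, 0.272 and 0.584 within the batches.

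Other splits of the 25 arrays into groups of 8, 12 and 5 showed how often such counts arise. Of 100 splits, the real one included, 4 gave as many probe sets as the 2 of high against low (highest other 17). For high against medium 3 gave as many as the 7 (highest other 40). For any difference 4 gave as many as the 2 (highest other 17), and for the trend 4 as many as the 1 (highest other 4). These shares lie narrowly under 0.05, for splits that ignore the batches and with no adjustment over the counts. Such counts are therefore uncommon among splits, and chance is not excluded for them. With labels shuffled within the spike-in batches, 1 of 100 gave as many for high against low (highest other 1), for high against medium (highest other 3) and for any difference (highest other 1), and 3 for the trend (highest other 1). With the batch as a block as well, 2 of 100 gave as many as the 2 of high against low (highest other 3) and 1 as many as the 4 of high against medium (highest other 3). For medium against low the real count was 0 (highest other 1), so all 100 splits gave as many by construction and the comparison says nothing about chance. At an unadjusted p under 0.05, 14 splits gave as many as the 1837 of high against low (highest other 3055), so chance cannot be excluded there, and 2 gave as many as the 2971 of high against medium (highest other 3085). List counts as large came from 64 splits for the 3 of high against low (highest other 12), 21 for the 7 of high against medium (highest other 13) and 93 for the 2 of medium against low (highest other 15), so chance cannot be excluded for any list count. Splits with 17 and 40 calls, several times the real counts, point to a structure of the samples, which was not tested. The split with 17 drew low 6 and medium 6, 7, 8 and 10 as high and the split with 40 drew low 1 and 2 and medium 1, 3 and 9. These were 0, 2 and 3 arrays and 2, 1 and 2 arrays of batches 1, 2 and 3, and the latter split held medium replicate 9, which stood apart, and 2 of the 3 ranked arrays of batch 1. The 5 arrays drawn as high in the split with 17 had the lowest immediate early list means of the 25. They ran from 7.78 in medium replicate 6 to 8.01 in medium replicate 10, and medium replicate 4 came next at 8.04. The 2 high comparisons share their 5 high arrays, and 3 of the other splits also called a probe set in both, at most 6, against the 1 real one, Bloc1s2.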
